A study of Homo sapiens with 6 samples.

How the data were processed

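The series holds 6 samples of 1 engineered cell line, U937T:PLZF-RARa, each on its own Affymetrix HG-U133 Plus 2.0 array: 3 uninduced and 3 induced for 48 h. Samples were grouped by their titles, which also carry the replicate numbers. The deposited table gives 1 intensity per probe set and array. These intensities were made with GCRMA, per the submitters' processing notes; GCRMA corrects the background from probe sequence, normalizes and summarises the probes of a probe set. The software version, whether all arrays were normalized together and any later scaling are not given in the sources used here. The deposited intensities were on a linear scale, from 0.913768 to 122290, with array medians of 8.05 to 8.41. The 75th percentile of the log2 values was 6.93 in uninduced replicate 3 and 7.12 to 7.19 on the other arrays, so the columns did not share a single distribution. GCRMA draws dim probe sets towards a common low value, so changes that start or end there are compressed or exaggerated in ways the table does not show.

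The log2 of each value was taken after raising the 6 values under 1 to 1. Of 54675 probe sets, 62 were Affymetrix controls and were left out of every comparison. GEO's platform annotation gave 1 gene symbol to 41091 probe sets, several to 1801 and none to 11721. No gene was named from a probe set with several symbols. Entrez identifiers of 41037 probe sets were found in the NCBI gene table, and 0 symbols needed an update. A probe set was tested where its log2 value was above 4 (an intensity of 16) on at least 3 of the 6 arrays, which left 20552. A gene was represented by its tested probe set with the highest mean over the 6 arrays, which gave 9836 genes, of which 4602 had over 1 tested probe set.

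Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. "Higher", "rose", "lower" and "fell" are used of genes past that threshold. The RARA probe set that failed the filter was taken from a fit with no filter. Fold changes are 2 to the power of the log2 difference. The table has no detection calls. Where all 3 arrays of a group lay at or below the filter, the fold is therefore given as "at least", the mean of the brighter group against a log2 value of 4, and the adjusted p is that of the fit on the measured values.

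Before the data were examined, 26 gene lists were written from general knowledge, with 1002 genes, of which 999 matched a current symbol. They cover the retinoic acid response, monocyte and macrophage differentiation, granule proteins, myeloid transcription factors, MYC targets, the cell cycle, p53 and CDK inhibitors, apoptosis, HOX and stem cell genes, interferon, NF-kB, MAPK, MHC class II, adhesion, lipid synthesis, protein and amino acid stress, the respiratory chain, mitochondrial translation, glycolysis and hypoxia, DNA repair, corepressors and chromatin, lymphoid markers, erythroid markers, heat shock and housekeeping genes. Lists with at least 5 measured members were tested with limma's camera with an inter-gene correlation of 0.01, adjusted over the 25 lists tested. Camera with the correlation estimated from the data and fry were run beside it. Counts for a list cover its measured members only. Members that were not measured failed the filter or had no probe set naming only that gene. The genes named were also fixed by rule before the data were examined: all RARA and ZBTB16 probe sets, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, up to 4 members per list with the smallest adjusted p, and MYC, DUSP6, CEBPA, CEBPE, CCNA1, SPI1, GFI1 and ID2. Others are said to have been chosen after their values were seen.

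RNA quality and array level were compared with two-sided exact permutation tests, for which 3 against 3 cannot give a p under 0.1. The alternatives were no filter, a filter at a log2 value of 6, quantile normalization and median centring of the arrays, a trended and robust eBayes, array weights, the replicate number as a block, the mean over a gene's probe sets, leaving out probe sets ending in _x_at or _s_at, which can bind several transcripts, leaving out each array in turn, and both other list tests. The fit was tested on simulated data with the means and spread of the 20552 probe sets of this comparison, in which 200 were changed. It recovered 54% of those changed by 0.5 on the log2 scale, 92% of those changed by 1, 96% of those changed by 2 and 98% of those changed by 4, with 7 wrong calls among 177. In 50 simulated lists camera recovered 5 of 5 moved by 0.5 and called 0 others; genes were drawn independently there, so this says nothing of false calls where genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome was used. A result on an item withheld from this text is not reported here.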

Results

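Gene expression was measured in U937T:PLZF-RARa, a derivative of the human monocytic line U937 that makes the fusion protein PLZF-RARA once tetracycline is taken out of the medium. PLZF-RARA joins ZBTB16 (PLZF), a transcriptional repressor, to the retinoic acid receptor RARA and is found in a rare form of acute promyelocytic leukaemia. RNA from 3 uninduced samples and from 3 samples induced for 48 h was hybridised to Affymetrix arrays, 1 array per sample. The design holds 1 comparison, induced against uninduced, which asks which transcripts change when the fusion is expressed. Arrays of the same group correlated at r = 0.9963 to 0.9976 over the 20552 probe sets above the filter, and arrays of different groups at r = 0.932 to 0.938. The median absolute difference between 2 arrays was 0.073 to 0.152 on the log2 scale within a group and 0.402 to 0.433 between groups. The 3' minus 5' log2 difference of the GAPDH control, a sign of RNA integrity, was 0.503 ± 0.025 (SD, n = 3) in uninduced and 0.579 ± 0.034 (SD, n = 3) in induced samples, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows. For the ACTB control it was 1.25 ± 0.08 (SD, n = 3) and 1.41 ± 0.10 (SD, n = 3), with an exact permutation p of 0.2. The labels number the replicates but do not say whether they were separate cultures, so p-values measure only the spread between these samples, and the number of arrays limits the precision.

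RARA signal rose in 1 of its 5 probe sets and ZBTB16 signal fell. The RARA probe set 211605_s_at went from a log2 intensity of 1.87 ± 0.10 in uninduced to 7.58 ± 0.17 in induced samples (SD, n = 3 each), at least 11.996-fold higher (limma, adjusted p = 1.90e-07). The RARA probe set 203749_s_at fell from 5.16 ± 0.08 to 3.99 ± 0.04, a change of -1.17 (adjusted p = 1.10e-05), with 2 of the 3 induced arrays above the filter. The RARA probe sets 203750_s_at and 216300_x_at differed by -0.22 and -0.12 and did not pass the test (adjusted p = 0.133 and 0.301), and 1565358_at lay at 1.91 in both groups, below the filter. The single ZBTB16 probe set, 205883_at, fell from 5.25 ± 0.21 to 3.29 ± 0.59, at least 2.38-fold lower (adjusted p = 8.11e-04). Which part of each transcript a probe set covers was not analysed here, so a probe set outside the sequence carried by the fusion says nothing about induction. After quantile normalization 203750_s_at and 216300_x_at passed the test, at -0.41 and -0.31; over all alternatives their adjusted p ranged from 0.0086 to 0.354 and from 0.010 to 0.814.

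**Figure D1:**
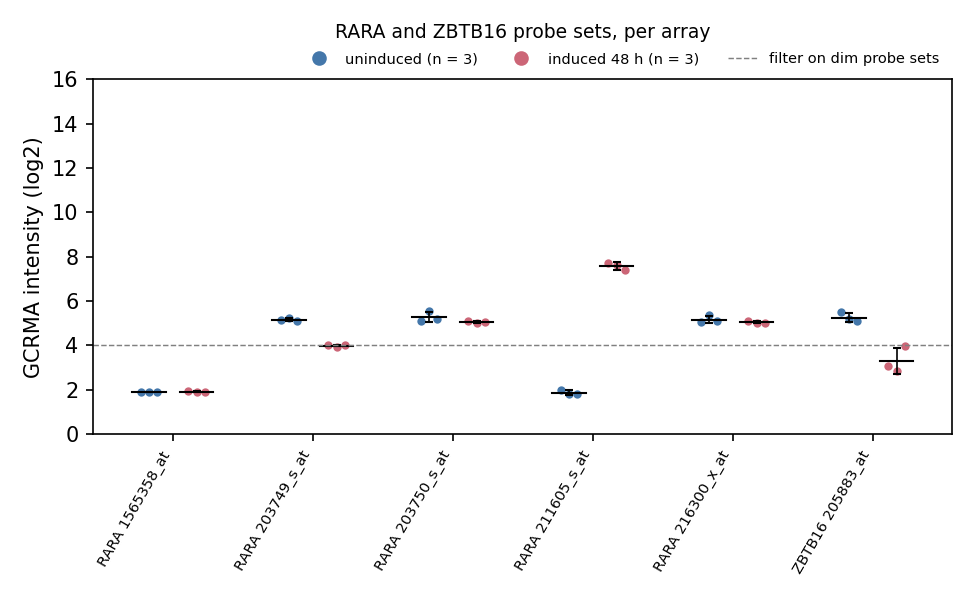
GCRMA intensity on the log2 scale (vertical axis) for each RARA and ZBTB16 probe set (horizontal axis) in 3 uninduced (blue) and 3 induced (red) arrays. Points are arrays, horizontal lines are group means, error bars are SD and the dashed line is the filter at 4. The induced arrays of RARA 211605_s_at average 7.58 against 1.87 in uninduced arrays.

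Ranked by the measured log2 difference, the GTPase RAB27B, which acts in vesicle secretion, came first among the rises and went from 2.33 ± 0.02 in uninduced to 10.25 ± 0.03 in induced samples (SD, n = 3 each), at least 76.0-fold higher (limma, adjusted p = 9.01e-09). It was followed by SPP1, the secreted phosphoprotein osteopontin (at least 47.3-fold), NBEA, a scaffold protein of membrane traffic (143-fold), the lymphoid cathepsin CTSW (at least 32.8-fold) and VIM, the intermediate filament vimentin (87.6-fold, from 7.21 ± 0.14 to 13.66 ± 0.07). CAMP, the precursor of the antimicrobial peptide cathelicidin (at least 38.5-fold), PRF1, the pore-forming protein perforin (at least 58.3-fold), EMP1, a membrane protein (at least 26.6-fold), the transcription factor WT1 (59.2-fold) and MILR1, an immunoglobulin-like receptor (at least 40.7-fold), completed the 10 genes taken from this rank. Of these 10 genes 7 lay below the filter in all uninduced arrays, where only the bound holds, so their order by fold is not established. At the other end EGR1, an immediate early transcription factor, went from 10.89 ± 0.06 to 3.36 ± 0.54, at least 119-fold lower (adjusted p = 1.36e-06). The calcium channel subunit CACNA2D3 fell from 10.04 ± 0.13 to 3.94 ± 0.45, PCOLCE2, an enhancer of procollagen processing, from 9.79 ± 0.06 to 3.80 ± 0.57, the neutrophil chemokine CXCL8 from 9.11 ± 0.03 to 4.02 ± 0.24 and the sphingosine kinase SPHK1 from 9.13 ± 0.12 to 4.26 ± 0.91. Of the 3 induced arrays 2 lay above the filter for CACNA2D3, 1 for PCOLCE2, 2 for CXCL8 and 2 for SPHK1, so no fold is given for them. The activin subunit gene INHBA was 32.2-fold lower. MS4A6A (at least 14.5-fold lower), the transcript METTL14-DT (at least 6.23-fold lower), ECE2, an endothelin-converting enzyme (23.3-fold lower), and NFE2, an erythroid and megakaryocytic transcription factor (at least 5.79-fold lower), made up the rest of the 10 falls taken from this rank, and the order of those given by a bound is not established either, nor that they fell more than genes measured in both groups.

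Of 20552 probe sets tested with limma, 7112 were higher and 5733 lower in induced samples, which is 62.5% in all. Lower calls were the more frequent after quantile normalization, with 6750 higher and 8113 lower, and after median centring, with 6579 and 7106. Counted by gene, 3519 of 9836 were higher and 3019 lower, and 1062 of the first and 868 of the second changed at least 2-fold. By gene 3442 were higher and 3984 lower after quantile normalization and 3257 and 3627 after median centring, so which direction held more calls depended on the scaling. The groups did not overlap in 74.4% of the genes, where chance gives 10%. For 155 of the 2685 genes with over 1 called probe set, these went both ways. Among the genes above, ECE2 rests on 1 of its 2 tested probe sets: without probe sets ending in _x_at or _s_at its change was -0.19 (adjusted p = 0.073, the highest of a range from 1.52e-08 over the alternatives). WT1 likewise rests on 1 of its 2 tested probe sets, as the other did not pass the test. The mean over a gene's probe sets gave a smaller rise for WT1, at 3.27 against 5.89 on the log2 scale.

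**Figure D2:**
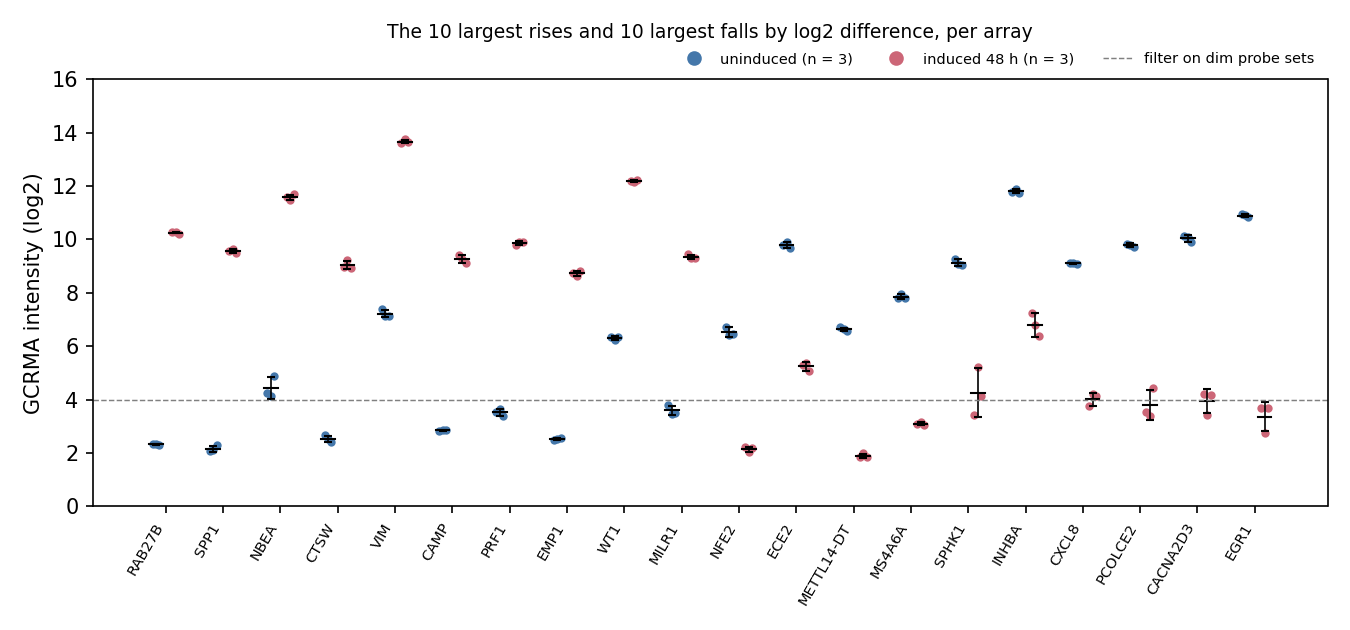
GCRMA intensity on the log2 scale (vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall by log2 difference (horizontal axis) in 3 uninduced (blue) and 3 induced (red) arrays. Points are arrays, horizontal lines are group means, error bars are SD and the dashed line is the filter at 4. The arrays of the 2 groups do not overlap for any of these genes, from RAB27B (2.33 against 10.25) to EGR1 (10.89 against 3.36).

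Transcription factors that drive myeloid differentiation changed in both directions. SPI1 (PU.1), a regulator of monocytes and granulocytes, fell from 7.12 ± 0.19 to 3.16 ± 0.33 (SD, n = 3 each), at least 8.70-fold lower (limma, adjusted p = 4.32e-06). CEBPE, a factor of late granulocyte maturation, was 10.0-fold lower (adjusted p = 9.04e-05) and CEBPA, which acts earlier in the same lineage, 2.64-fold lower (adjusted p = 1.98e-05). IRF8, a factor of monocyte development, was 5.86-fold lower, LYL1 4.36-fold lower and the repressor GFI1 1.34-fold lower. ID2, an inhibitor of helix-loop-helix factors, was 1.25-fold higher (adjusted p = 0.0031), and 2 of its 2 tested probe sets rose. In the list of myeloid transcription factors 10 of 30 measured members rose, 16 fell and 4 did not pass the test, and the list as a whole did not shift past the threshold (camera, adjusted p = 0.195).

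MYC, a transcription factor of growth and ribosome production, fell from 12.86 ± 0.07 to 9.35 ± 0.04 (SD, n = 3 each), an 11.4-fold decrease (limma, adjusted p = 2.16e-07). Of 49 measured genes in the list of MYC targets, which holds MYC itself, 45 fell and 2 rose, with a median log2 change of -1.31. The ribosome assembly genes NOP16 (4.28-fold lower) and RRS1 (4.43-fold lower) and the pseudouridine synthase PUS7 (4.50-fold lower) had the smallest adjusted p after MYC. The list shifted down (camera, adjusted p = 9.95e-15), and the adjusted p was 0.625 with an estimated correlation. Genes of mitochondrial translation fell in 45 of 53 cases and rose in 1, with a median of -0.65. Among them were the ribosomal proteins MRPS2 (3.79-fold lower), MRPL4 (3.57-fold lower) and MRPL24 (2.49-fold lower) and the initiation factor MTIF2 (2.08-fold lower). That list shifted down as well (camera, adjusted p = 4.83e-10; adjusted p = 0.625 with an estimated correlation).

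Genes of the unfolded protein and amino acid stress response fell in 30 of 37 cases and rose in 4. The glutathione-degrading enzyme CHAC1 was at least 3.03-fold lower, the cystathionine lyase CTH 5.76-fold lower and the stress-induced growth inhibitor DDIT4 4.35-fold lower, while the stress factor ATF3 was 5.99-fold higher. The list shifted down (camera, adjusted p = 4.38e-06; adjusted p = 0.625 with an estimated correlation). Of 17 heat shock and chaperone genes 11 fell and 2 rose. The mitochondrial chaperone HSPA9 was 2.35-fold lower, CHORDC1 2.03-fold lower and HSPH1 1.71-fold lower, while DNAJB4 was 2.59-fold higher. Its shift passed the threshold (camera, adjusted p = 0.016; adjusted p = 0.71 with an estimated correlation).

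Genes of the G2 phase and mitosis rose in 36 of 44 cases and fell in 2, by a median of 0.57 on the log2 scale. The kinetochore motor CENPE was 2.39-fold higher, the cytokinesis regulator ECT2 2.40-fold, the kinetochore protein NDC80 2.19-fold and the spindle motor KIF11 1.98-fold. CCNA1, a cyclin of germ cells and some leukaemias, was 1.75-fold higher (limma, adjusted p = 1.95e-04). The list shifted up (camera, adjusted p = 2.20e-06; adjusted p = 0.625 with an estimated correlation). Inhibitors of cyclin-dependent kinases and p53 targets rose in 20 of 28 cases and fell in 2. CDKN2B (p15) was at least 7.21-fold and CDKN2D (p19) at least 5.71-fold higher, the cyclin-like inhibitor CCNG2 was 10.7-fold and the p53 target SESN1 3.47-fold higher. This list shifted up too (camera, adjusted p = 3.80e-04; adjusted p = 0.625 with an estimated correlation). The genes of the G1 to S transition and DNA replication went both ways, with 13 of 43 up and 11 down, or 13 and 10 adjusted over the list alone and 11 and 15 after median centring. CCNE2 (3.55-fold higher), E2F2 (3.98-fold), E2F8 (2.66-fold) and CCND3 (2.88-fold) led it, and the list did not pass (camera, adjusted p = 0.826). Its median was -3.2e-04, while its mean, 0.16, and the direction of the test were positive. DNA repair genes rose in 9 and fell in 18 of 48 cases, with NTHL1 3.58-fold, PMS1 2.76-fold and APEX1 2.32-fold lower and LIG4 2.58-fold higher, and did not pass as a list (adjusted p = 0.258).

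Apoptosis regulators rose in 18 and fell in 7 of 28 cases, or 18 and 8 adjusted over the list alone, and the list missed the threshold (camera, adjusted p = 0.052). The death ligand TNFSF10 (TRAIL) was at least 15.6-fold higher, BNIP3L 2.93-fold, CASP4 2.63-fold and CASP8 2.03-fold higher. Without induced replicate 1 the shift of this list passed (adjusted p = 0.0471), as it did with no filter (0.0036) and with a trended and robust eBayes (0.0489), in a range up to 0.160 over the alternatives.

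Granule proteins of granulocytes fell in 11 of 13 cases. The serine protease PRTN3 went from 13.50 ± 0.10 to 10.19 ± 0.02 (SD, n = 3 each), 9.90-fold lower, the protease inhibitor SERPINB1 was 10.9-fold and MS4A3 5.40-fold lower, and CAMP was the 1 member that rose. The list shifted down (camera, adjusted p = 3.44e-04; adjusted p = 0.625 with an estimated correlation). Of 46 markers of monocyte and macrophage differentiation 18 were measured, of which 13 rose and 5 fell. Those that did not pass the filter included CD14 (2.10 in uninduced and 2.09 in induced samples) and CSF1R (3.17 in both). FCER1G, a signalling chain of Fc receptors, was 18.3-fold and the scavenger receptor CD36 15.9-fold higher, beside SPP1. The calcium-binding protein S100A8 rose from 4.22 ± 0.29 to 8.13 ± 0.15, with 2 of the 3 uninduced arrays above the filter, so no fold is given for it. The list shifted up (camera, adjusted p = 0.033; adjusted p = 0.625 with an estimated correlation). It did not pass with no filter (adjusted p = 0.236), with a stricter filter (0.081) or without probe sets ending in _x_at or _s_at (0.237), and the lowest over the alternatives was 0.017. Among leukocyte adhesion and chemotaxis genes 13 of 22 rose and 5 fell. ITGA6 (at least 16.5-fold), the chemokine receptor CX3CR1 (11.4-fold) and ANXA1 (10.7-fold) were higher and ALCAM was 9.67-fold lower, and the list did not pass (adjusted p = 0.092), but did with no filter (0.039, in a range up to 0.141 over the alternatives). Of 7 genes of MHC class II presentation 1 rose and 2 fell, or 1 and 4 after quantile normalization, with CD74 1.496-fold and HLA-DMA 2.66-fold lower, RFX5 1.25-fold higher and HLA-DPA1 differing by -0.25 (limma, adjusted p = 0.092; 2 of the 3 induced arrays above the filter), and the list did not pass (adjusted p = 0.416). RFX5 did not pass with the mean over its probe sets (0.14 on the log2 scale; limma, adjusted p = 0.084, the highest of a range from 0.0014 over the alternatives). HLA-DPA1 passed after quantile normalization (-0.39, limma, adjusted p = 0.029) and with the replicate number as a block (-0.25, adjusted p = 0.0499), in a range up to 0.257 over the alternatives.

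Of 44 interferon-stimulated genes 31 were measured. Of these 23 rose and 4 fell, or 24 and 5 adjusted over the list alone, with a median of 1.13 on the log2 scale. Those that did not pass the filter included MX1 (2.48 in uninduced and 2.47 in induced samples), IFI27 (1.91 in both), IFI44L (2.06 and 2.05) and OASL (2.91 and 3.13). The antiviral proteins IFIT1 and IFIT2 were at least 14.1-fold and at least 29.0-fold higher, the DNA sensor IFI16 was 13.1-fold and the ISG15 protease USP18 4.68-fold higher. The list shifted up (camera, adjusted p = 2.02e-04; adjusted p = 0.625 with an estimated correlation). NF-kB and inflammatory cytokine genes went both ways, 8 up and 7 down of 17. PTX3, a soluble pattern recognition protein, was 31.0-fold and the inhibitor TNFAIP3 4.29-fold higher, while CXCL8 and SOD2 (3.29-fold) were lower. The list did not pass (adjusted p = 0.949), and its median (0.11) and mean (0.25) were positive while the test pointed down. MAPK feedback and target genes rose in 12 and fell in 3 of 21 cases. The ERK phosphatase DUSP6 was 3.34-fold (limma, adjusted p = 3.17e-06) and DUSP4 4.68-fold higher and DUSP2 was 6.59-fold lower. This list missed the threshold (camera, adjusted p = 0.078) and passed with no filter (0.0489), with a stricter filter (0.0394) and after median centring (0.0486), in a range up to 0.247 over the alternatives.

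Of 29 genes of the retinoic acid response 12 were measured, of which 5 rose and 4 fell. The others had no probe set naming only that gene or did not pass the filter. Among the latter were RARB (2.88 in both groups) and CYP26A1 (2.39 in both). A fall could not be seen in them, so the list result covers the measured genes only. TNFSF10 rose, and PRAM1 (5.97-fold), BHLHE40 (7.06-fold) and the retinol dehydrogenase RDH10 (3.53-fold) were lower. The list did not shift (camera, adjusted p = 0.949). Corepressors and chromatin regulators rose in 22 and fell in 5 of 40 cases. The deacetylase HDAC9 was at least 10.1-fold higher, the acetyltransferase KAT2B 4.18-fold, the coactivator NCOA1 3.30-fold and the DNA methyltransferase DNMT3B 2.18-fold higher. KAT2B and NCOA1 are known as activators of transcription rather than corepressors. The list shifted up (camera, adjusted p = 0.037; adjusted p = 0.77 with an estimated correlation) and did not pass with a stricter filter (0.060), with the mean over a gene's probe sets (0.068) or without probe sets ending in _x_at or _s_at (0.16), and the lowest over the alternatives was 0.0012. Of 37 HOX and stem cell genes 7 were measured, of which 4 rose and 1 fell, or 4 and 2 after quantile normalization. MEIS1 was 3.42-fold, MLLT3 2.42-fold and CD44 2.18-fold higher and SOX4 2.03-fold lower, and the list did not pass (camera, adjusted p = 0.279). None of the HOXA genes was measured: HOXA2 did not pass the filter and the others had no probe set naming only that gene. HOXB4, CD34, KIT and FLT3 did not pass the filter either.

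Markers of other blood lineages were mostly below the filter. Of 29 T, B and NK cell markers 6 were measured and 4 rose: PRF1, the cytotoxic granule protein NKG7 (6.58-fold), the adhesion molecule NCAM1 (2.17-fold) and the pre-B cell receptor chain VPREB1 (1.74-fold). None fell, and 1 did after quantile normalization. The list did not pass (camera, adjusted p = 0.089). Of 23 erythroid and megakaryocyte markers 3 were measured, too few for the test. KLF1 was at least 2.79-fold lower, while TFRC differed by -0.05 and EPOR by 0.003, neither past the threshold (limma, adjusted p = 0.563 and 0.967). After quantile normalization EPOR passed at -0.16 (adjusted p = 0.036, the lowest over the alternatives).

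Genes of energy and lipid metabolism did not shift as lists. Subunits of the mitochondrial respiratory chain rose in 9 and fell in 16 of 45 cases, or 7 and 16 adjusted over the list alone, with ATP5MC1 2.49-fold, COX5A 1.68-fold, NDUFA10 1.603-fold and NDUFB10 1.504-fold lower (camera, adjusted p = 0.258). The counts were 12 up and 17 down after quantile normalization and 2 up and 20 down after median centring. In glycolysis and hypoxia 8 of 28 rose and 12 fell, or 9 and 12 adjusted over the list alone. The glucose transporter SLC2A3 was 12.8-fold higher, the hypoxia factors EPAS1 and HIF1A were at least 6.72-fold and 2.52-fold higher, and the angiogenic factor VEGFA was 4.22-fold lower (adjusted p of the list 0.555). Its median, -0.07, and the test pointed down while its mean was 0.10. Cholesterol and fatty acid synthesis genes rose in 11 and fell in 6 of 23 cases, with HMGCS1 2.12-fold and STARD4 1.67-fold higher and DHCR7 3.24-fold lower (adjusted p of the list 0.416). The desaturase SCD was 1.90-fold lower, and 2 of its 2 tested probe sets fell. Of 24 housekeeping genes 7 rose and 4 fell, or 6 and 4 adjusted over the list alone, with YWHAZ 1.57-fold, REEP5 1.497-fold and CHMP2A 1.36-fold higher and GPI 2.14-fold lower (adjusted p of the list 0.567). In the other 20 lists the counts adjusted over the list alone were those given.

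In all, 5 of 25 lists shifted up and 5 down with the correlation between genes preset at 0.01, and 0 of 25 passed in limma's camera with an estimated correlation, where the smallest p was 0.107 before and 0.625 after adjustment. By fry, which asks only whether a list's genes move one way on balance, 19 of 25 passed.

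**Figure D3:**
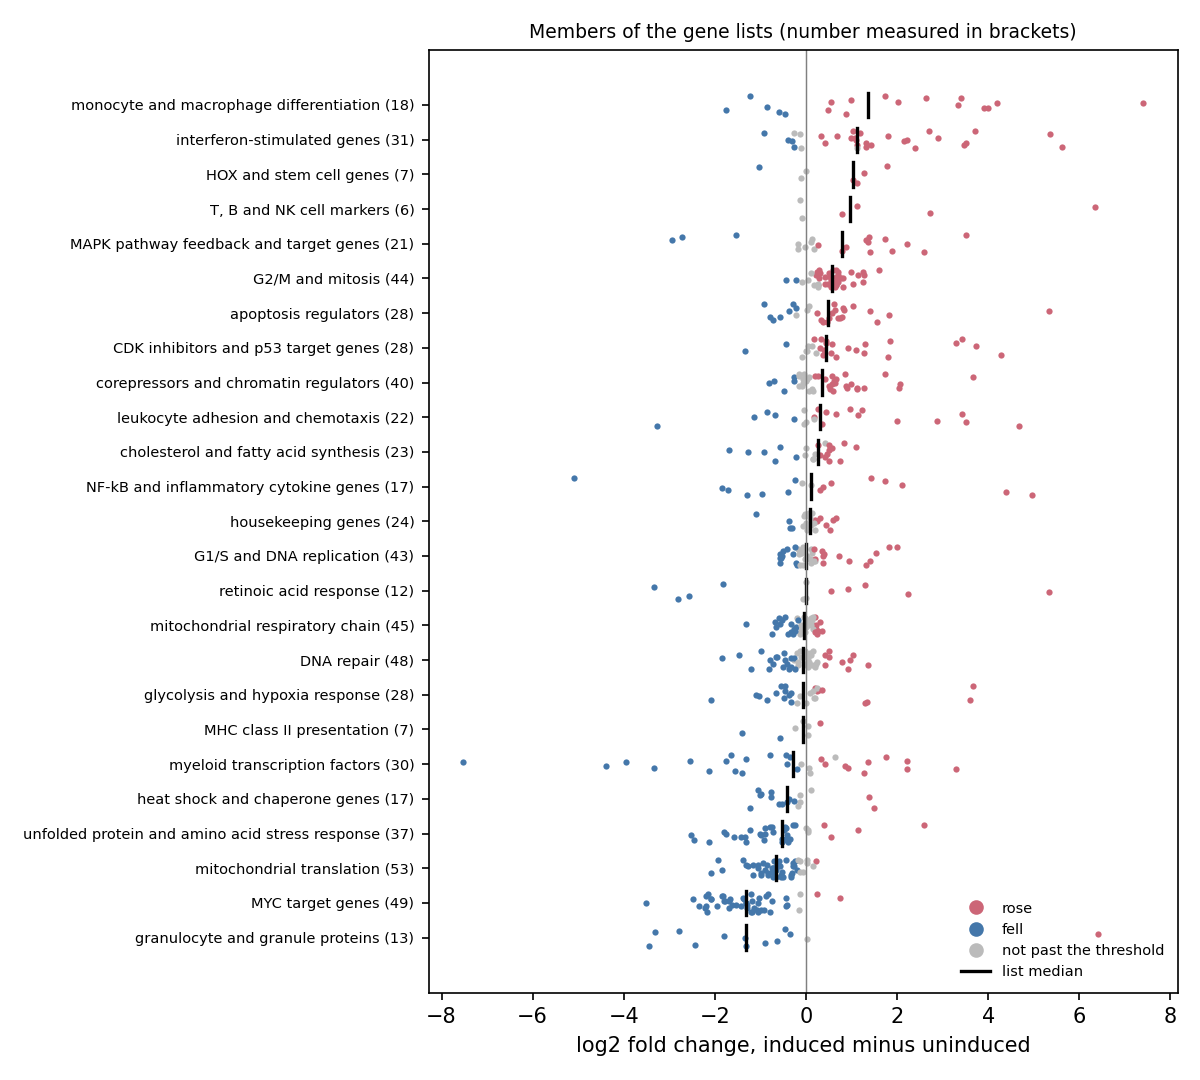
Log2 fold change, induced minus uninduced (horizontal axis), of each measured member of the 25 gene lists tested (vertical axis, number measured in brackets). Points are genes, red where they rose, blue where they fell and grey where they did not pass the test, and black bars are list medians. Nearly all MYC target genes lie to the left of 0 (median -1.31) and most interferon-stimulated genes to the right (median 1.13).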

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

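The tests below were chosen after the results were seen, except that of RNA quality. In this comparison 62.5% of the probe sets were called. Poorer RNA in a group needs its 3' minus 5' differences to part widely. Their group means differed by at most 0.158 (ACTB), under the limit of 0.5 set beforehand. The GAPDH differences of the arrays did not overlap, however, at 0.481 to 0.530 in uninduced and 0.555 to 0.619 in induced arrays. A shift of a whole group by the normalization needs the 18 bacterial hybridisation controls to move with it. Their median absolute group difference was 0.058 against 0.688 for called probe sets. Cells of another line with gained or lost chromosomes need whole chromosomes to move, and the chromosome farthest from the median of all genes, 15, lay at 0.0997 (bootstrap SE 0.035), under the limit of 0.2, while a simulated single-copy gain in a diploid chromosome, 0.585, put 23 of 23 chromosomes past 0.3, and a smaller gain of 0.292 put 12 of 23 past 0.3 and 23 past 0.2. The fusion, the removal of tetracycline itself or both stay open as the source. They cannot be told apart because 0 arrays hold cells without the fusion gene. The labels name no batch of culture or array processing, so a difference of that kind between the groups was not tested. With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real split called 12845 probe sets, 6538 genes and 1930 genes changed at least 2-fold. It was the 1 split of the 10 to reach each of these. The highest other called 0, 0 and 0 with limma (313 probe sets at an unadjusted p under 0.05, against 13599). Each other split puts induced and uninduced arrays into the same group, which widens the spread within it. Few calls were thus bound to result there, so this contrast is no evidence against chance.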

How the results depend on the processing

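No alternative was added after the data were seen for these results. Over the alternatives other than leaving out an array, 1039 of 1047 values of named genes, 240 of 271 of lists and 102 of 111 counts and target probe sets kept their direction and side of the threshold, or stayed within 1.5 times for counts; with each array left out in turn these were 724 of 726, 149 of 150 and 81 of 84. Without probe sets ending in _x_at or _s_at, which leaves fewer to test, 4365 probe sets were higher and 3172 lower, and 3 lists shifted up. With an estimated correlation 0 lists shifted up and 0 down, and by fry 12 shifted up. RARA 203750_s_at passed at -0.41 after quantile normalization and at -0.30 after median centring, and RARA 216300_x_at at -0.31 after quantile normalization. RARA 1565358_at, at the floor of the arrays, ranged from -0.011 to 0.0065 with an array left out. EPOR turned to -0.16 after quantile normalization, past the threshold (adjusted p = 0.036), and -0.076 after median centring, and ranged from -0.0096 to 0.014 with an array left out. Without _x_at and _s_at probe sets the values obtained under the names ID2, -0.015, and SCD, 0.40, cannot be those genes' own. In the main fit 2 of 2 tested probe sets of ID2 rose and 2 of 2 of SCD fell. These values are among those of named genes counted as changed. Whether values of other named genes in that setting are affected was not checked. The retinoic acid list passed fry with the direction up, although its mean stayed at -0.022. The cause of these changes was not tested, nor where the values under the names ID2 and SCD came from. Same-numbered arrays deviated from their group means with correlations of -0.173, 4.6e-04 and 0.180. Differently numbered arrays of different groups ranged from -0.238 to 0.209. So few pairs cannot settle whether the numbers pair the samples, and the labels do not say. With the replicate number as a block 7099 probe sets were higher and 5710 lower, and of the named genes and lists 1 changed its call, HLA-DPA1 (adjusted p = 0.0499). Signals near the background set the limit for dim genes, for which a fold is only a bound.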

Other observations

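The gene families and all tests of this section were chosen after the data were seen. For lymphoid markers and for variation between arrays, the limits were set before those tests were run.

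Of 30 aminoacyl-tRNA synthetases, which charge tRNAs, 26 fell and 1 rose, with a median log2 change of -0.66; the largest falls were those of MARS2 (5.43-fold lower) and VARS1 (3.89-fold lower), chosen after their values were seen (camera, adjusted p = 3.70e-07; adjusted p = 0.621 with an estimated correlation). Of 16 subunits of RNA polymerases I and III 13 fell and 2 rose, by a median of -0.87 (adjusted p = 1.52e-04; adjusted p = 0.621 with an estimated correlation). Of 57 cytosolic ribosomal proteins 1 rose, 9 fell and 47 did not pass, with a median of -0.07, and 18 of 58 fell after quantile normalization and 26 of 57 after median centring (adjusted p = 0.0497; adjusted p = 0.768 with an estimated correlation).

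Of 17 measured histone genes 12 rose and 1 fell (adjusted p = 0.0084; adjusted p = 0.621 with an estimated correlation). S100 proteins and annexins, which bind calcium, rose in 11 and fell in 2 of 17 cases, with a median of 0.82 (adjusted p = 0.015; adjusted p = 0.621 with an estimated correlation). Semaphorins, plexins, ephrins and their receptors rose in 9 and fell in 1 of 17 cases, or 8 and 3 after quantile normalization, led by PLXNC1 (log2 change 4.63) and EFNB2 (3.63), chosen after their values were seen (adjusted p = 0.022; adjusted p = 0.621 with an estimated correlation). The direction of the median of each of these 6 families was the same after quantile normalization and after median centring. In all 17 families were tested, and several not described here also passed with the preset correlation. Nucleolar processing factors had the smallest adjusted p, with 73 of 111 lower and 21 higher (camera, adjusted p = 3.27e-07, or 0.621 with an estimated correlation). The 238 zinc finger genes with ZNF symbols went both ways, 63 up and 67 down, or 59 and 102 after quantile normalization (camera, adjusted p = 0.601). Their median of 0.0011 became -0.15 after quantile normalization and -0.078 after median centring.

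The lymphoid genes PRF1, CTSW and CD96 rose together. CD96, chosen after its values were seen, went from 3.20 ± 0.09 to 7.62 ± 0.18 (SD, n = 3 each). T or NK cells in the induced cultures need their other abundant transcripts to rise with them. For this test 11 further markers were fixed before it was run, all members of the T, B and NK list above. Their median log2 change was -0.0024, with 10 of 11 below the filter in induced arrays. The other, NKG7, lay above the filter in uninduced cells already and rose from 7.67 to 10.39. In induced arrays CD3D lay at 2.19, GNLY at 2.37 and GZMB at 2.47. RNA from such cells was thus argued against, and expression of these genes by the induced cells themselves may be the source, as a hypothesis found and examined on the same data.

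The lists of MYC targets and of mitochondrial translation both shifted down with the preset correlation, and for each the adjusted p was 0.625 with the correlation estimated from the data, at 0.460 and 0.533. Variation between arrays that a list's genes share needs the list's mean to vary within the groups, and for MYC targets the group difference was 21.3 times the pooled SD of that mean between arrays, over the limit of 10 set beforehand. For mitochondrial translation it was 10.5 times, over that limit by less than the uncertainty of an SD from so few arrays. That ratio alone does not decide. The list's mean per array was 11.17 to 11.31 in uninduced and 10.56 to 10.64 in induced samples. Median centring, which removes a level shared by a whole array, left 48 of 53 genes lower and 0 higher. Centring does not remove variation shared by this list's genes alone. The means per array are those behind the ratio, so they are no separate test. The gap between the groups exceeds the spread within them. This argues only against variation of the size seen between these replicate arrays as the source of this list's fall. Larger variation between cultures or batches was not tested. The fusion, through the fall of MYC or otherwise, and the removal of tetracycline, which may act on mitochondrial translation, cannot be told apart for this list, with 0 arrays of cells without the fusion gene. The real split of the arrays gave 10 shifted lists and 2 of the 10 splits gave as many, with 6 to 10 lists in the splits other than the real one, and 10 splits are too few for a share under 0.05; every other split still sets unequal numbers of induced arrays against each other.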
